A study of Homo sapiens with 6 samples.

How the data were processed

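The data were RNA immunoprecipitation sequencing (RIP-seq) of HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Per the labels' protocols, cells received 4 µg of plasmid for Flag-tagged IGF2BP1, IGF2BP2 or IGF2BP3 at 24 hours after plating. They were later crosslinked with UV light, and sonicated nuclear extract was incubated with 1 µg of Flag antibody on magnetic beads. RNA recovered from the beads (IP) and from the extract (input) was made into strand-specific libraries by the dUTP method. For each of the 3 proteins there was 1 input and 1 IP library, 6 libraries in 6 groups, each assigned from its title.

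FPKM values (fragments scaled to transcript length and to the mapped fragments of the library) for input and IP were given by the authors in 4 deposited sheets. There was 1 sheet per protein and 1 for genes found with all 3 proteins. The submitters' processing notes name FastQC 0.11.4, cutadapt 1.9.1, TopHat2 2.0.13, Cuffdiff 2.2.1 and the hg19 build. The role and order of these tools, the gene annotation, the strand setting and any further scaling between libraries are not given in the sources used here. The authors' deposited log2 fold change equalled the log2 ratio of IP FPKM to input FPKM, with no pseudocount, within 0.0001 for every gene. The sheet for all 3 proteins held exactly the genes shared by the single sheets, and its 6 FPKM columns were equal to theirs, so it was used only for this check.

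The sheets list bound genes selected by the authors. Every listed gene had an input FPKM above 0.5 and an authors' deposited log2 fold change above 1; further criteria of the selection are not given in the sources used here. A gene missing from a sheet can have failed any criterion, so its absence is no measurement. Genes outside the sheets were not analysed here, and the listed genes cannot show what share of all transcripts was recovered. FPKM values do not give the number of fragments, so the depth of each library is unknown and no counting interval was computed. FPKM also magnifies very short RNAs, whose values depend strongly on fragment size and transcript length. An IP from cells without a Flag-tagged protein was not analysed here.

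From these values the enrichment of each gene was computed as log2((IP FPKM + 1)/(input FPKM + 1)), and as the corresponding fold. The pseudocount of 1 lowers the enrichment of genes with low input. With 1 library per group, differences have no replicate check and no p-value was computed. The tables were intersected by gene symbol, and the union held 8309 symbols. No expected overlap was computed, because the genes tested by the authors are not part of the sheets. Pearson and Spearman correlations were taken across genes, which are not independent replicates. Medians were given a 95% order-statistic interval across genes. It describes how closely the median over many genes is placed, and neither the much wider spread between genes nor that between cultures. In the IGF2BP1 table, for example, the quartiles of the log2 enrichment were 1.87 and 2.90.

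In all, 34 gene lists, covering RNA and protein families, pathways, targets of the IGF2BP proteins and markers of other cells, were fixed before the data were examined. A list with at least 5 members in a table was compared with 10000 random lists of the same size, drawn from that table and matched on mean expression in 10 bins. A list was called above its random lists at the 97.5th percentile or higher, and below them at the 2.5th or lower. This percentile describes these libraries and is no test between conditions. The procedure was tested on simulated lists of 40 genes, 200 for each shift and table, a number raised after a first run with fewer lists had called more of the unshifted IGF2BP2 lists. With no shift, 1.5% (IGF2BP1), 3.5% (IGF2BP2) and 5.5% (IGF2BP3) of lists were called above, so the nominal 2.5% was exceeded in 2 tables. A shift of 0.5 on the log2 scale was called in 93.0%, 75.0% and 61.5% of lists, and a shift of 1 in 100% in each table. The simulation used fewer random lists than the 10000 used for the data, and added the shift after the expression bins had been set. In the data a higher IP value also raises the mean expression used for matching. These rates can therefore overstate how often a real shift is called, and they cover lists of 40 genes only.

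Genes to be named were set by rules fixed before the data were examined. For each protein these were the 10 largest folds among genes with at least 1 FPKM in both libraries and the 10 highest IP values. For each pair of proteins they were the 5 genes per direction with the largest difference in enrichment. The 3 transfected genes, all members of the target lists and up to 4 members of each other list completed them. Some genes taken by these rules are not reported here singly, though the list counts and medians include them. Symbols were matched to GENCODE release 29 for gene type, transcript length and gene span, and 7745 of the 8309 symbols matched (93.2%). That annotation is on another build (GRCh38) than the sheets, so no coordinates are printed. Overlaps between named genes and other genes were counted within that annotation. Transcript length was first the longest transcript and was changed, after results had been seen, to the longest protein-coding transcript of protein-coding genes.

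The alternatives fixed beforehand were a pseudocount of 0.1 or none, minimum values, a 4-fold threshold, the authors' deposited fold change, scaling of IP and input to the same median, each IP against the mean of the 3 inputs over genes common to all 3 tables, and other matching of random lists. Matching on transcript length or on intron length, each in place of mean expression, and on expression with length in 5 bins each was added after the data had been seen. So were the restrictions to protein-coding genes, to the IGF2BP2 and IGF2BP3 tables and, for gene lists with the own input, to genes common to all 3 tables. Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.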

Results

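RNA recovered with the m6A-reading, mRNA-stabilising proteins IGF2BP1, IGF2BP2 and IGF2BP3 was surveyed in HEK293T cells that had received a plasmid for 1 of these proteins with a Flag tag. Each protein had 1 input library of nuclear extract and 1 IP library, so 6 libraries were compared in 3 pairs. There are no replicates, and all comparisons describe these libraries only. The authors' tables of bound genes held 6227 genes for IGF2BP1, 5486 for IGF2BP2 and 6029 for IGF2BP3. Protein-coding genes made up 91.2%, 90.5% and 91.7% of them. The depth of the libraries is unknown, because the values are FPKM.

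The transcripts of the transfected genes were examined first, as a check of the labels. IGF2BP2 had an input FPKM of 395 in its own libraries, 48.2 times its value in the IGF2BP1 input (8.20) and 53.3 times that in the IGF2BP3 input (7.40). IGF2BP3 had an input FPKM of 369 in its own libraries and 15.8 in the IGF2BP1 input, a ratio of 23.3. IGF2BP1, in contrast, had an input FPKM of 28.5 in its own libraries and 21.4 in those of IGF2BP3, a ratio of 1.33. In the IPs, IGF2BP2 reached 47385 FPKM and IGF2BP3 15617 FPKM with their own protein, whereas IGF2BP1 reached 172 FPKM with its own protein and 102 FPKM with IGF2BP3. IGF2BP1 and IGF2BP3 were not listed in the IGF2BP2 table. IGF2BP2 was thus highest in the libraries labelled for it, and IGF2BP3 was higher in its own libraries than in those of IGF2BP1, the only others that list it. For the libraries labelled IGF2BP1 the transcript gave no clear check, and every result given for IGF2BP1 rests on that label. Whether plasmid transcripts that lack the genomic untranslated regions were counted in full is not known.

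**Figure D1:**
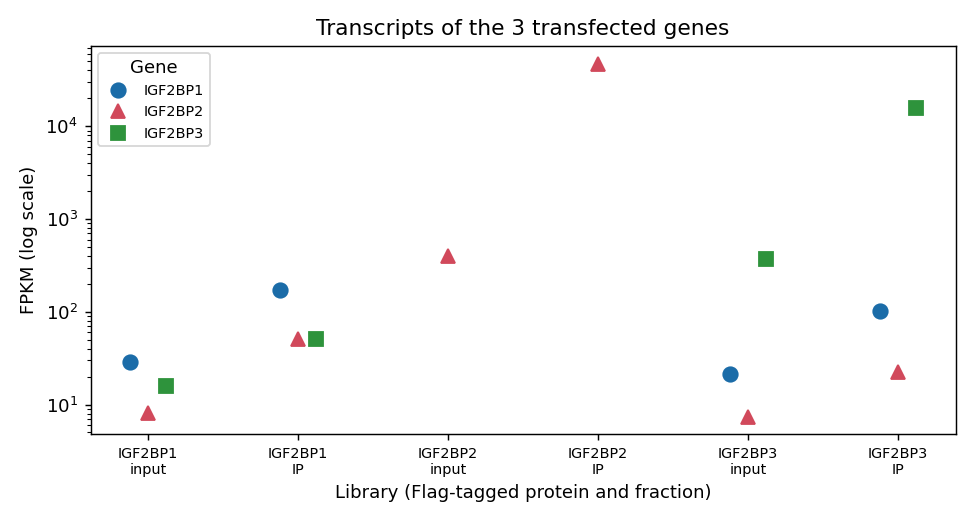
FPKM on a log axis of the IGF2BP1, IGF2BP2 and IGF2BP3 transcripts in the 6 libraries, 1 point per listed value; a gene not listed in a table has no point there. IGF2BP2 and IGF2BP3 stand at 395 and 369 FPKM in their own inputs, and IGF2BP1 at 28.5 FPKM in its own input.

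Which transcripts were recovered with IGF2BP1 was asked by comparing its IP with its input. Messenger RNAs of the translation machinery and of histones were prominent. Cytosolic ribosomal protein genes were listed for 74 of 79 members, with a median 13.8-fold higher FPKM in IP than in input; RPL31 went from 39.4 to 1844 FPKM and RPLP2 from 44.9 to 1680. Replication-dependent histone genes, whose mRNAs end in a stem-loop instead of a poly(A) tail, were listed for 32 of 61 members at a median of 19.0-fold, with HIST1H3B at 45.8-fold and HIST1H4D at 32.0-fold. Translation factors had a median of 9.91-fold over 35 of 39 members, including EEF2, the translocation factor, at 10.9-fold and EIF6 at 21.2-fold. Nuclear-encoded subunits of the respiratory chain and ATP synthase had a median of 7.42-fold over 52 of 74 members, with UQCRQ at 44.5-fold. Host transcripts of small nucleolar RNAs had a median of 13.1-fold over 15 of 18 members, led by SNHG1 at 48.4-fold.

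Across all genes of the IGF2BP1 table the median log2 enrichment was 2.33 (95% interval across genes 2.31 to 2.36), a 5.04-fold difference, and 4255 genes reached 4-fold. The groups named above lay above their matched random lists, as did glycolysis (median 11.3-fold, 14 of 19 listed; LDHB 24.8-fold), genes of the G1/S transition (7.29-fold, 32 of 41; FEN1 13.8-fold) and small noncoding RNAs (31.8-fold over 23 genes). The list of nuclear and structural noncoding RNAs (16.0-fold, 10 of 18) was also above; its named members RN7SL1, the RNA of the signal recognition particle, and TERC, the telomerase RNA, stood at 1028-fold and 35.6-fold. Zinc finger genes of the ZNF family were the 1 list below its random lists in this table, with a median of 4.01-fold over 118 genes (percentile 0.06), although ZNF236 reached 65.4-fold. Among genes common to all 3 tables, the ZNF list (percentile 7.33), the G1/S list (86.0) and the nuclear and structural noncoding RNAs (74.4, 5 members) were no longer called, still with the own input. Against the mean of the 3 inputs over the same genes, the ZNF list (9.77) and the G1/S list (74.9) were not called either.

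With IGF2BP2 the same comparison again placed the translation machinery and histones high. Cytosolic ribosomal protein genes were listed for 72 of 79 members at a median of 47.5-fold; RPL31 went from 4.64 to 1442 FPKM and RPS15 from 3.87 to 1055. Replication histones had a median of 49.8-fold over 32 of 61 members, with HIST1H3B at 306-fold. Translation factors stood at 15.5-fold over 33 of 39 members, with EEF2 at 118-fold, and respiratory chain subunits at 16.0-fold over 45 of 74, with ATP5B, the catalytic beta subunit of ATP synthase, at 80.2-fold. Glycolytic genes had a median of 21.7-fold over 15 of 19 members, ENO1 and GAPDH standing at 61.7-fold and 55.6-fold.

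The median log2 enrichment in the IGF2BP2 table was 2.63 (interval 2.60 to 2.67), or 6.21-fold, and 4127 genes reached 4-fold. Besides the groups named for this protein, those above their random lists were G1/S genes (10.9-fold, 29 of 41; MCM5, a subunit of the replicative helicase, 24.9-fold), the ER and secretory list (10.3-fold, 34 of 48; P4HB, a protein disulfide isomerase, 30.2-fold), tubulins (20.4-fold, 5 listed; TUBA1B 48.8-fold), small noncoding RNAs (65.8-fold over 32 genes) and nuclear and structural noncoding RNAs (50.0-fold, 9 of 18; RN7SK 50.0-fold). With a pseudocount of 0.1, G1/S genes (percentile 95.4), glycolysis (96.7) and the ER list (93.1) were no longer called. Among genes common to all 3 tables, with the own input, the ER list (93.5), glycolysis (96.5) and the nuclear and structural noncoding RNAs (97.1, 5 of the 9 members left) lost the call, and G1/S genes kept it (99.0). With the mean of the 3 inputs over the same genes, G1/S genes (74.4), the ER list (97.0) and the nuclear and structural noncoding RNAs (67.9) were not called. The ER list also lost the call with matching on expression and transcript length (95.3), and the tubulins with matching on intron length (96.2).

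For IGF2BP3, ribosomal protein genes were listed for 76 of 79 members at a median of 55.9-fold; RPS15 went from 2.85 to 1409 FPKM and RPL31 from 9.36 to 1808. Replication histones had a median of 42.6-fold over 21 of 61 members, with HIST1H2BD at 322-fold. Translation factors stood at 18.4-fold over 34 of 39 members and respiratory chain subunits at 14.4-fold over 51 of 74, ATP5O reaching 340-fold. Genes of the unfolded protein and stress response had a median of 14.6-fold over 16 of 24 members; ATF4, a transcription factor of the integrated stress response, went from 0.957 to 108 FPKM and HSPA8, a constitutive chaperone, from 5.01 to 246. This list stood at 6.11-fold with IGF2BP1 (15 of 24) and 10.3-fold with IGF2BP2 (12 of 24), within random lists (percentiles 81.4 and 95.6), but above them for both against the mean of the 3 inputs over genes common to all tables (97.63 and 97.7). For IGF2BP2 it was also above among those genes with the own input (98.5) and with a pseudocount of 0.1 (97.92).

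The median log2 enrichment in the IGF2BP3 table was 2.69 (interval 2.66 to 2.72), or 6.45-fold, and 4676 genes reached 4-fold. Further lists above their random lists were G2/M genes (11.9-fold, 34 of 51; CKAP5, a spindle protein, 39.6-fold), spliceosome genes (14.4-fold, 42 of 49; SNRPB 61.8-fold), small nucleolar RNA hosts (19.8-fold, 14 of 18; SNHG1 152-fold), tubulins (20.2-fold, 5 listed; TUBB 38.2-fold) and small noncoding RNAs (137-fold over 23 genes). Among genes common to all 3 tables, with the own input, spliceosome genes (percentile 92.6) and the hosts (94.8) were no longer called, and G2/M genes were (98.5). With the mean of the 3 inputs over the same genes, G2/M genes (85.9), spliceosome genes (73.0) and the hosts (96.9) were not called, and with matching on intron length the tubulins were not (91.0). The ZNF list (5.13-fold over 105 genes) was within its random lists for IGF2BP3, but below them with matching on input (0.055), on transcript length (0.685) or on intron length (0.10) and with no matching (0.13).

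Over the 3 proteins, 5 lists were above their random lists in every table: cytosolic ribosomal proteins, replication histones, translation factors, respiratory chain subunits and small noncoding RNAs. Of 81 results from 27 lists, 30 were above and 1 below. Ribosomal proteins, histones and small noncoding RNAs kept the call in every alternative that gave a value. Respiratory chain subunits lost it in all 3 tables when random lists were matched on expression and transcript length together (percentiles 93.0, 97.4 and 78.6). That matching left out members without a match to the annotation, such as ATP5B and ATP5O. For IGF2BP3 they also lost it among genes common to all 3 tables, with the own input (96.9) and with the mean of the 3 inputs (92.3). Translation factors lost it among those genes with the mean of the 3 inputs for IGF2BP2 (89.4) and IGF2BP3 (94.7), but not with the own input (98.7 and 99.1). Lists above for part of the proteins were within their random lists for the others. These were G2/M and spliceosome genes with IGF2BP1 (6.48-fold and 7.71-fold) and IGF2BP2 (9.27-fold and 12.2-fold), the ER list with IGF2BP1 (6.48-fold) and IGF2BP3 (9.81-fold), tubulins with IGF2BP1 (6.77-fold), hosts of small nucleolar RNAs with IGF2BP2 (9.91-fold), and G1/S genes (7.63-fold), glycolysis (17.7-fold) and nuclear and structural noncoding RNAs (18.1-fold) with IGF2BP3. Some of these were above under other settings. Glycolysis with IGF2BP3 was so among genes common to all 3 tables with either input (97.87 and 99.1), spliceosome genes with IGF2BP1 with the mean input over those genes (97.51) and with a pseudocount of 0.1 (98.1), and G2/M genes with IGF2BP2 with that pseudocount (98.3) and among protein-coding genes (97.74). The differences between proteins were not tested. For ribosomal proteins the folds differed between tables mainly through the inputs. The 70 ribosomal protein genes in all 3 tables had median IP values of 596, 555 and 594 FPKM with IGF2BP1, IGF2BP2 and IGF2BP3 and median inputs of 40.1, 10.3 and 8.81 FPKM. Their medians against the mean of the 3 inputs were 26.7-fold, 27.3-fold and 26.3-fold. With random lists matched on input instead of mean expression, 45 results were above and 5 below, and the spliceosome, glycolysis, G2/M and ER lists were then above with every protein. Nuclear and structural noncoding RNAs with IGF2BP3 were then above as well (97.96). Matched on transcript length instead, spliceosome (99.99 and 100) and G2/M genes (98.1 and 98.2) were above with IGF2BP1 and IGF2BP2. So were the ER list with IGF2BP1 (98.1) and IGF2BP3 (98.7) and glycolysis with IGF2BP3 (99.96). Ribosomal protein, histone and tubulin genes have near-identical copies or pseudogenes, so their single-gene values are uncertain.

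**Figure D2:**
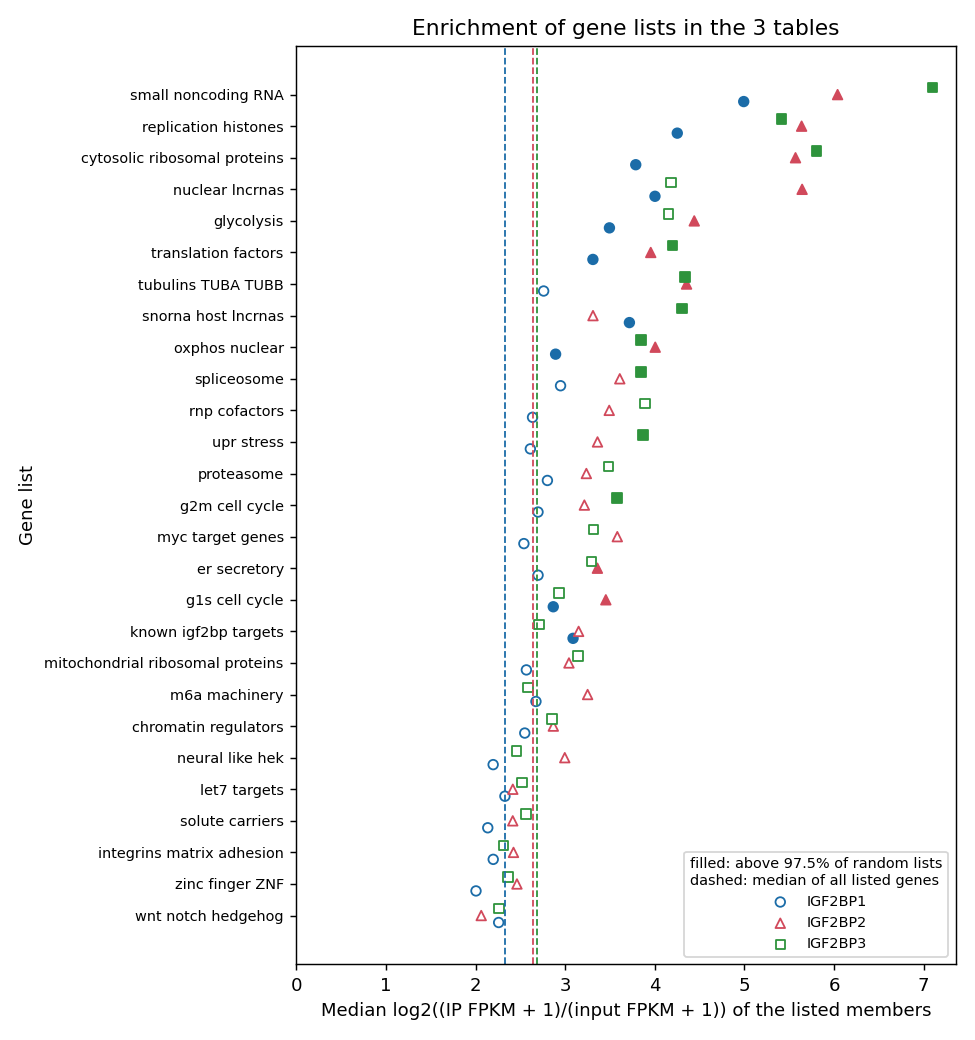
Median log2((IP FPKM + 1)/(input FPKM + 1)) of the listed members of 27 gene lists, 1 symbol per protein; filled symbols were called above their matched random lists and dashed lines mark the median of all listed genes. Ribosomal proteins, replication histones and small noncoding RNAs are filled for all 3 proteins, at 13.8-fold or more for ribosomal proteins; the ZNF list for IGF2BP1, which was below its random lists, is drawn open.

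Noncoding RNAs and names without a match held most of the largest ratios. RNA5-8SP6, a pseudogene of 5.8S ribosomal RNA, stood at 208-fold with IGF2BP1, 1335-fold with IGF2BP2 and 8612-fold with IGF2BP3. RN7SL3, a copy of the signal recognition particle RNA, stood at 206-fold, 922-fold and 1583-fold. The U4 RNA RNU4-2, a spliceosomal RNA, had 37.5-fold, 173-fold and 853-fold, and SCARNA2, a guide RNA of Cajal bodies, 383-fold, 323-fold and 574-fold. For RNU4-2 the inputs were 442, 158 and 20.2 FPKM and the IPs 16616, 27506 and 18105 FPKM, so its folds differed between IGF2BP1 and IGF2BP3 mainly through the inputs. The 10 small noncoding RNAs in all 3 tables had medians of 34.5-fold, 142-fold and 309-fold with the own input and 67.0-fold, 110-fold and 73.7-fold with the mean of the 3 inputs. AC004943.1, annotated as antisense, had 111-fold, 1796-fold and 1995-fold, and the unmatched name AL161626.1 63.5-fold, 249-fold and 2247-fold. Between IGF2BP1 and IGF2BP3 these folds, and that of RNA5-8SP6, also differed mainly through the inputs. Inputs fell from 855 to 89.6 FPKM for AC004943.1, from 11830 to 401 for AL161626.1 and from 6139 to 387 for RNA5-8SP6. The IPs went from 95198 to 180874, from 751722 to 903675 and from 1.28e+06 to 3.34e+06 FPKM. The 10 largest folds per protein were taken among genes with at least 1 FPKM in both libraries. Protein-coding genes among them were ADRM1 for IGF2BP1 (110-fold), EXOC3, PRPF19, HIST1H3B and LSM4 for IGF2BP2 (626-fold, 527-fold, 306-fold and 298-fold) and FBRSL1 for IGF2BP3 (943-fold). ADRM1 with IGF2BP2 (463-fold) and SCARNA2 with IGF2BP1 had inputs under that limit (0.832 and 0.867 FPKM) and were not ranked for those proteins. The 10 genes with the highest IP values held 85.7%, 89.3% and 91.6% of the summed IP FPKM of the tables, and 0 of these 10 matched a protein-coding gene in any table. Copies of 5.8S, U2, U4 and signal recognition particle RNA share reads, so these values are uncertain. Of 174 named genes matched to the annotation, 114 overlap another annotated gene, 63 of them on the same strand. FBRSL1 overlaps 3 genes and SNHG1 7 genes on the same strand, whereas EXOC3 (3 genes) and ADRM1 (2 genes) overlap others only on the opposite strand. The libraries were strand-specific, but the strand setting of the processing is not given, so overlaps of either kind leave a value uncertain.

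Known targets of the IGF2BP family were then examined. MYC, whose coding region holds an instability element bound by IGF2BP1, went from 3.71 to 46.4 FPKM with IGF2BP1, from 0.918 to 52.1 with IGF2BP2 and from 1.39 to 35.7 with IGF2BP3. ACTB, the beta-actin mRNA bound through its zipcode, had log2 enrichments of 3.90, 6.55 and 5.02, and MKI67, a proliferation marker, of 4.37, 5.16 and 6.01. CTNNB1 had 3.36, 3.15 and 3.58, CDK6 had 3.09, 4.39 and 4.51, and E2F1 had 3.35, 4.22 and 4.20. BTRC and CCND2, with the 6 genes named so far, made 8 of the 23 members listed in all 3 tables; 16 were in at least 1 table and 7 (IGF2, CD44, GLI1, MAPK4, ABCB1, FOXM1 and PEG10) in none. Some were listed for part of the proteins, such as HMGA1 (4.44 and 5.14 with IGF2BP1 and IGF2BP2), CCND1 and CCND3 (2.29 and 1.40 with IGF2BP2, 2.71 and 2.56 with IGF2BP3), LIN28B (1.37 and 2.58 with the same proteins) and HMGA2 (2.46 with IGF2BP1 and 2.45 with IGF2BP3). SRF was 4.60-fold and 4.21-fold higher in IP than in input with IGF2BP1 and IGF2BP3.

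Each table listed 13 of the known targets, though not the same 13. As a list they had medians of 8.50-fold, 8.87-fold and 6.53-fold, above random lists for IGF2BP1 (percentile 99.3) and within them for IGF2BP2 (92.7) and IGF2BP3 (58.4). The 8 targets in all 3 tables, compared with common genes alone, were above for IGF2BP2 and IGF2BP3 as well, with the own input (99.96 and 99.2) and with the mean of the 3 inputs (99.98 and 99.7). The difference between proteins was not tested. A further list of 3 genes recalled as targets from the study itself, FSCN1 (2.36, 3.54 and 1.98), TK1 (2.71, 3.27 and 3.46) and MARCKSL1 (4.01, 4.90 and 4.49), was listed in full in all 3 tables. The study may have picked them from these libraries, so they are not independent evidence. Every listed gene passed the authors' threshold, so a value below the median of its table, such as BTRC with IGF2BP2 at 1.63, is low only among listed genes.

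How far the 3 proteins shared their listed transcripts was asked from the overlap of the tables. Of 8309 genes in the union, 3729 (44.9%) were in all 3 tables, which is 68.0% of the smallest table. These included 70 of the 79 cytosolic ribosomal protein genes and 32 of the 39 translation factors. IGF2BP1 shared 4341 genes with IGF2BP2 and 4570 with IGF2BP3, and IGF2BP2 shared 4251 with IGF2BP3. Genes in the IGF2BP1 table alone numbered 1045, in the IGF2BP2 table alone 623 and in the IGF2BP3 table alone 937. Genes listed for a single protein had lower median folds (3.93, 3.98 and 4.41 for IGF2BP1, IGF2BP2 and IGF2BP3) than common genes (5.80, 7.42 and 8.43) and lower median IP values (16.8, 11.5 and 16.3 against 40.4, 32.3 and 38.1 FPKM). Without the tested background, the overlap has no expected value, and a gene of a single table is not shown to be bound by that protein alone.

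**Figure D3:**
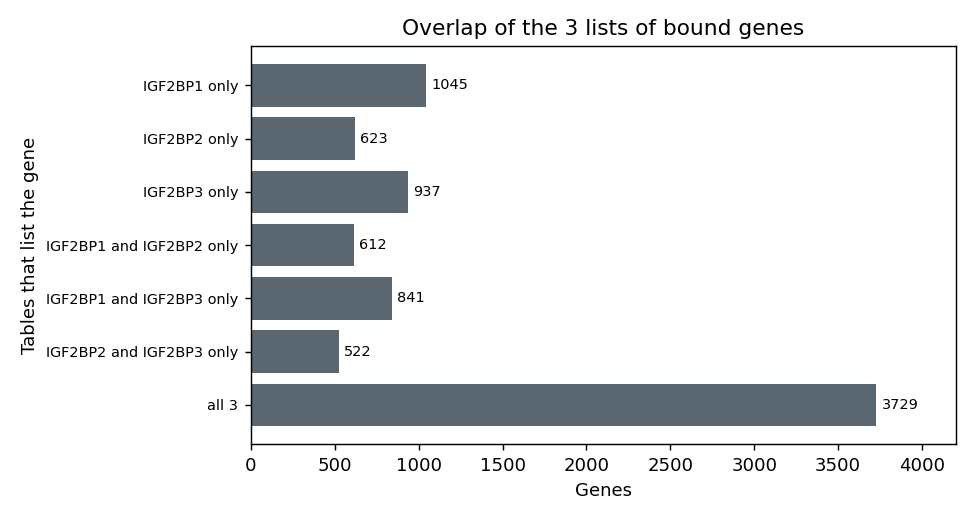
Number of genes in each part of the overlap of the 3 tables of bound genes, as bars on a linear axis from 0. The 3729 genes in all 3 tables form the largest part, and the parts of a single table hold 1045, 623 and 937 genes.

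Between proteins, enrichment was compared gene by gene among the genes listed for both proteins of a pair. SRP54, a protein of the signal recognition particle, had a log2 enrichment of 7.31 with IGF2BP3 and 2.34 with IGF2BP2. PRPF19, a splicing factor, had 9.04 with IGF2BP2 and 3.80 with IGF2BP1, and PTP4A1, a phosphatase, had 7.21 and 2.86. Genes higher with IGF2BP1 than with IGF2BP2 included NPRL2 (4.14 and 1.30), LARP7, which binds 7SK RNA (4.22 and 2.06), and ADAM10, a membrane protease (3.98 and 1.96); those higher with IGF2BP1 than with IGF2BP3 included SF3A3, a splicing factor (3.87 and 1.53), ZNF276 (4.24 and 1.96) and SEC63 (3.56 and 1.60). NCBP3 (4.43 and 1.63), SEPT11 (4.93 and 2.21) and RPL13 (6.83 and 4.17) were higher with IGF2BP2 than with IGF2BP3. The 7SK RNA RN7SK stood at 9.39 with IGF2BP3 and 3.42 with IGF2BP1, mostly through its inputs (15.7 and 602 FPKM), as its IP values were 11205 and 6456 FPKM. The PRPF19 difference also lay more in the inputs (2.82 and 41.9 FPKM) than in the IPs (2013 and 598 FPKM), whereas for SRP54 the IPs differed (619 and 9.66 FPKM). The input part exceeded the IP part on the log2 scale in 13 of the 29 reported differences with the largest size, RPL13 (inputs of 5.75 and 18.3 FPKM) among them. None of the 29 has a replicate check.

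Over the 3729 genes common to all 3 tables, Pearson's r of the log2 enrichment was 0.71 for IGF2BP1 with IGF2BP2, 0.66 for IGF2BP1 with IGF2BP3 and 0.70 for IGF2BP2 with IGF2BP3 (Spearman's rho 0.63, 0.59 and 0.61), across genes that are not independent replicates. The median difference was 0.41 for IGF2BP2 minus IGF2BP1 (95% interval across genes 0.38 to 0.45), 0.54 for IGF2BP3 minus IGF2BP1 (0.50 to 0.57) and 0.18 for IGF2BP3 minus IGF2BP2 (0.14 to 0.20). The median input of the common genes was 6.14 FPKM with IGF2BP1, 3.08 with IGF2BP2 and 3.28 with IGF2BP3. When each IP was set against the mean of the 3 inputs, the differences from IGF2BP1 turned to -0.34 for IGF2BP2 and -0.16 for IGF2BP3.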

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

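Each IP was compared with its own input, but no paired test within a protein was possible, because each protein had 1 pair of libraries. A fit over the 3 pairs was not run. It would take different proteins as replicates, and every common gene was selected for a higher IP in each pair. The restrictions to protein-coding genes, the restriction to 2 tables, the gene lists among genes common to all 3 tables with the own input and the matching on transcript or intron length were chosen after the data had been seen. So was the measure of change for medians and correlations, their 95% interval across genes, which replaced a fixed tolerance. The median log2 enrichments for IGF2BP1, IGF2BP2 and IGF2BP3 became 2.60, 3.05 and 3.10 with a pseudocount of 0.1, and 2.64, 3.13 and 3.17 with none or with the authors' deposited fold change. Among genes with a mean of at least 5 they were 2.39, 2.81 and 2.82. Scaling IP and input to the same median, which removes any overall enrichment by construction, took them to 0.0015, -0.10 and -0.14 and the genes at 2-fold to 849, 1016 and 1173 (6210, 5470 and 6021 before). Relative to the medians so removed, 16 of the 52 reported values of target and transfected genes turned negative: BTRC (-0.91 with IGF2BP2, -0.97 with IGF2BP3), CCND1 (-0.74, -0.27), CCND2 (-0.39, -1.35) and CCND3 (-1.60, -0.55) with the same proteins, LIN28B (-0.88) with IGF2BP2, FSCN1 (-0.70), HMGA2 (-0.65), SRF (-0.12), IGF2BP1 (-1.06) and IGF2BP2 (-1.66) with IGF2BP3, and IGF2BP1 (-0.048) and IGF2BP3 (-0.96) with IGF2BP1. The overlap of all 3 tables was 2442 genes at 4-fold or more in each, since fewer genes entered. Pearson's r was 0.68, 0.63 and 0.67 with a pseudocount of 0.1 (IGF2BP1 with IGF2BP2, IGF2BP1 with IGF2BP3, IGF2BP2 with IGF2BP3) and 0.68, 0.63 and 0.68 over protein-coding genes. With that pseudocount the median difference from IGF2BP1 was 0.58 for IGF2BP2 and 0.69 for IGF2BP3. Against the mean of the 3 inputs it reversed to -0.34 and -0.16, IGF2BP3 minus IGF2BP2 was 0.22 and r of IGF2BP1 with IGF2BP3 was 0.71. That mean was the same for every protein, so these differences compared the IP values alone. The shared input also entered both sides of r, so the higher r is no sign of closer likeness between the proteins. The causes of the other changes were not tested. The number of list results above their random lists was 30, and 25 to 45 under the alternatives. The mean of the 3 inputs was used only over genes common to all 3 tables; of 75 results over these genes 26 were above with it and 26 with the own input, where 9 calls were lost and 6 gained. A list left with fewer than 5 members, such as tubulins, gave no value there, and among protein-coding genes alone small noncoding RNAs gave no value. The unknown depth leaves the precision of low FPKM values open.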

Other observations

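For other gene groups the call depended in part on how random lists were matched. Cofactors of ribonucleoprotein granules had medians of 6.21-fold, 11.2-fold and 14.8-fold with IGF2BP1, IGF2BP2 and IGF2BP3, within random lists matched on mean expression but above with IGF2BP2 (percentile 99.1) and IGF2BP3 (99.9) when matched on input, and PABPC1, the poly(A)-binding protein, stood at 14.0-fold, 47.3-fold and 90.5-fold. Genes of the m6A machinery were listed for 15, 9 and 11 of 19 members at 6.38-fold, 9.51-fold and 6.01-fold, within random lists; the nuclear m6A reader YTHDC1 had 20.0-fold, 13.7-fold and 5.40-fold. Mitochondrial ribosomal proteins (5.92-fold, 8.23-fold and 8.84-fold; 37, 32 and 33 of 74 listed), proteasome subunits (6.97-fold, 9.42-fold and 11.2-fold), targets of the transcription factor MYC (5.81-fold, 12.0-fold and 9.97-fold) and chromatin regulators (5.85-fold, 7.29-fold and 7.23-fold) were within random lists in all 3 tables. Among genes common to all 3 tables, proteasome subunits were above with IGF2BP2 with the own input (99.2) and with the mean of the 3 inputs (99.4), and with IGF2BP3 with the own input (98.8); mitochondrial ribosomal proteins were above with IGF2BP3 only with the mean input (99.8). With matching on input, MYC targets were above with IGF2BP2 (99.9) and IGF2BP3 (99.6) and proteasome subunits with all 3 proteins (98.6, 97.53 and 99.5), and with matching on intron length chromatin regulators were (99.6, 98.8 and 98.1). Also within were let-7 targets, the transfected genes IGF2BP2 and IGF2BP3 among them (5.02-fold, 5.33-fold and 5.72-fold), and integrin and matrix genes (4.58-fold, 5.36-fold and 4.96-fold). So were genes of the Wnt, Notch and Hedgehog pathways (4.78-fold, 4.18-fold and 4.79-fold) and solute carriers (4.39-fold, 5.33-fold and 5.90-fold). A list set up as neural-type genes of HEK293T cells, which also holds VIM and KRT18, was within too (4.58-fold, 7.97-fold and 5.48-fold). Of these lists, with matching on input, the Wnt, Notch and Hedgehog list was below with IGF2BP2 (1.03) and IGF2BP3 (2.43) and solute carriers with IGF2BP1 (1.42), and with a pseudocount of 0.1 integrin and matrix genes were below with IGF2BP3 (1.71).

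Few markers of other cells were listed. Hepatocyte markers had 1, 1 and 3 of 15 members with IGF2BP1, IGF2BP2 and IGF2BP3, erythroid markers 0, 0 and 1 of 12, leukocyte markers 1, 1 and 2 of 14 and fibroblast markers 1, 1 and 2 of 11. FGG, a fibrinogen chain made in liver, had input values of 0.675, 1.38 and 2.23 FPKM. Interferon response genes were listed for 3, 2 and 1 of 26 members, IRF7 at 4.61-fold and 2.10-fold with IGF2BP1 and IGF2BP2. Of 28 mitochondrially encoded genes 2, 2 and 4 were listed, the ribosomal RNA MT-RNR2 at 7.28-fold, 15.7-fold and 56.5-fold. Too few members were listed for a comparison with random lists.

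In the weighing of patterns that follows, the tests on expression with length, on the IGF2BP1 transcript and on the inputs were chosen after their results had been seen, and matching on length or introns after the data had been seen. The first pattern is the 5 lists above their random lists with every protein. In protein-coding genes enrichment fell with transcript length (Spearman's rho -0.18, -0.19 and -0.18 across genes). It also fell with intron length, slightly more strongly (-0.212, -0.218 and -0.215). With random lists matched on transcript length 15 of the 15 results stayed above, and with matching on intron length 15 of 15. Each of these matchings replaced the match on expression, and with no matching at all more results were above than in the main setting (45 against 30). Intron length was not matched together with expression, so unspliced RNA in the input as a source is not decided by this. Matched on transcript length together with abundance, 12 of 15 stayed and 0 of the 3 respiratory chain results did. Members without a match to the annotation, ATP5B and ATP5O among them, were left out there and in the matching on length or introns alone. Short and abundant transcripts may therefore account for the call of that list only as far as its members were matched. The joint match used 5 length bins and the longest annotated transcript, so short transcripts can share a bin with longer ones. Calls kept by histones and ribosomal proteins therefore do not show that length and abundance were fully matched. For small noncoding RNAs the length match is especially coarse, because few listed genes are as short. Recovery by the beads or the antibody without the tagged protein was not tested, so preferred binding of the other lists by the IGF2BP proteins is a hypothesis that stays open, and translation factors also lost 2 of 3 calls against the mean of the 3 inputs over genes common to all tables.

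The second pattern is the IGF2BP1 transcript, which in its own input was only 1.33 times its value in the IGF2BP3 input. An exchange with the IGF2BP2 or IGF2BP3 libraries is argued against, since in the IGF2BP1 input these genes had at most 0.0429 of the value in their own inputs. Endogenous IGF2BP1 hiding a fully counted overexpression of the size seen for IGF2BP3 is argued against too, as the input held 0.0762 of the 375 FPKM needed. This rests on the same low input value, and whether plasmid transcripts were counted in full is not known. A plasmid transcript that was not counted as IGF2BP1 cannot be told apart from weak expression: IGF2BP1 in its own IP was 1.69 times that in the IGF2BP3 IP, and no value here separates plasmid from chromosomal reads. Whether the tagged protein was made in those cells stays untested.

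The third pattern is the larger enrichment with IGF2BP2 and IGF2BP3 than with IGF2BP1. Against its own input, the median of the common genes was 0.36 higher with IGF2BP2 and 0.54 higher with IGF2BP3. Against the mean of the 3 inputs the excess was -0.40 and -0.19. That mean is the same for every protein, so only the IPs differ. Their medians were 40.4, 32.3 and 38.1 FPKM with IGF2BP1, IGF2BP2 and IGF2BP3. The excess against the own input thus lay in the lower IGF2BP2 and IGF2BP3 inputs by arithmetic, which is no test of a cause. IPs are also hard to compare, since 10 genes held 85.7%, 89.3% and 91.6% of the summed IP FPKM. Why these inputs were lower was not tested. A difference between the proteins stays open and untested, since each protein had its own single input.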
